A study of Faecalibacterium prausnitzii with 12 samples.

How the data were processed

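RNA was sequenced from *Faecalibacterium prausnitzii* strain A2-165, an anaerobic gut bacterium that ferments sugars to butyrate, grown in YCFAG, a rich medium for gut anaerobes. Per the labels' protocols, total RNA was extracted with acid phenol and chloroform, depleted of ribosomal RNA and made into whole-transcriptome libraries. The 12 libraries form 4 groups of 3: without added calcium palmitate (CP0) at 5 h and at 16 h, with it at 0.01 mg/mL (CP2) at 16 h, and a group titled CP2 at 5 h. Calcium palmitate is the calcium salt of palmitic acid, a saturated fatty acid. Groups, times and replicate numbers were taken from the sample titles. For the 3 libraries titled CP2 at 5 h, another label field states no calcium palmitate and 16 h; the titles were followed, no dose was assigned to these libraries, and they are called the libraries labelled CP2 at 5 h. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

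The deposited table holds a normalized signal per gene, namely read counts that the authors divided by 1 size factor per library, for 2910 genes in 12 columns. Trim Galore, STAR and DESeq2 are named per the submitters' processing notes, without versions or roles. The genome build, the annotation and the read counter are not given in the sources used here, nor is whether counting used strand, so reads of overlapping, antisense or near-identical genes cannot be told apart. Whole reads were recovered by taking the smallest non-zero value of each column as 1 read and refining that unit against the larger values. All non-zero values (100%) came out whole within 0.01 reads, and size factors recomputed from the recovered reads by the median of ratios matched the deposited scaling to within 3.2e-09 percent. Such scaling sets the typical gene to no change between libraries, so a shift shared by most genes cannot be seen. The recovered totals, 12428812 to 24788164 reads per library, give the depth behind each value. Within groups, replicates differed by more than counting noise in every pair (chi-square per degree of freedom 17.38 to 291.92), so no library was treated as a copy of another.

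The main test was limma (3.58.1, R 4.3.3) with a mean-variance trend on log2(value + 1), fitted to all 12 libraries with 1 mean per group, over the 2693 genes with a mean value of at least 10. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were CP2 against CP0 at each time, the difference of these treatment changes (the interaction), and 16 h against 5 h within CP0 and within CP2. Log2 changes and folds are on the log2(value + 1) scale, which understates changes of low genes; adjusted p-values are from limma unless another tool is named. Reads were simulated once, from the CP0 means at each time with 1 dispersion per gene for all groups, and 2671 genes were tested. For the 16 h comparison limma recovered 49.3% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 97% of those changed 4-fold. Of its 158 calls, 4 were false. For the 5 h comparison it recovered 44.8%, 80.6% and 97%, with 11 of 159 calls false. The simulated reads lack the wider replicate spread at 16 h and hold fewer changed genes than were called in the data. These rates may therefore not carry over. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

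The table identifies genes by locus tag and does not pair tags with gene names. The gene lists fixed in advance (among them fatty acid synthesis, phospholipid synthesis and butyrate synthesis) therefore could not be matched, and their tests were not run. Before the data were examined, the rule for named genes was fixed as the largest changes each way among called genes with a mean of at least 50 and, for comparisons of 2 groups, no overlap between groups; with no gene names, at most 2 tags that rose and 2 that fell were to be printed per comparison, and this limit was applied. The largest changes in the text are largest among genes that met this rule. Gene groups are described as runs: called genes with consecutive tag numbers, 5 apart, that changed in the same direction. Tags in the table rise in order, and neighbouring tags were taken as neighbouring genes, which was not checked against a genome. Run counts were set against 1000 shuffles of the genes' order. Such shuffles separate neighbours that change together for any reason, so an excess of runs is not particular to the treatment.

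Alternatives fixed before the data were examined were other pseudocounts, other filters, rescaling to equal totals or upper quartiles, a replicate block, a fit with only the libraries compared, a 2-fold limit, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, and leaving out each library. Thinning every library to the smallest total and a test of position along the tag order were added after the data were seen. The correlation of changes across comparisons that share libraries was set beside 100 simulations with no effect.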

Results

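Transcript levels were measured for 2910 genes of *F. prausnitzii* A2-165 in 12 RNA-seq libraries, 3 per group, from cultures without (CP0) and with (CP2) calcium palmitate, sampled at 5 h and 16 h. The dose was 0.01 mg/mL in CP2 at 16 h, and none was assigned to the libraries labelled CP2 at 5 h, whose labels conflict. Recovered totals were 23031037 to 23272524 reads per library in CP0 at 5 h, 22686035 to 24788164 in the libraries labelled CP2 at 5 h and 22527494 to 23866105 in CP0 at 16 h. The CP2 libraries at 16 h were shallower, with 12428812 to 15261281 reads. The 10 most abundant genes took 19.37% to 22.22% of the normalized counts in each library. Between 11 and 22 genes were listed at 0 per library at 5 h, and between 57 and 92 at 16 h. The median SD of log2 values among replicates was 0.075 in CP0 at 5 h, 0.115 in CP2 at 5 h, 0.209 in CP0 at 16 h and 0.201 in CP2 at 16 h.

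The first principal component held 74.6% of the variance and separated the 5 h libraries (-49.13 to -39.38) from the 16 h libraries (35.55 to 52.75). The libraries titled CP2 at 5 h, for which another label field states 16 h, lay among the 5 h libraries. The second component, with 15.3% of the variance, separated CP0 (-27.22 to -25.92) from CP2 (25.69 to 32.13) at 16 h, whereas the 5 h libraries lay between -3.51 and 1.27. Replicate 3 of CP2 at 5 h stood apart on the third component (3.2% of the variance), at 25.1 against 4.65 and 1.65 for replicates 1 and 2.

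**Figure D1:**
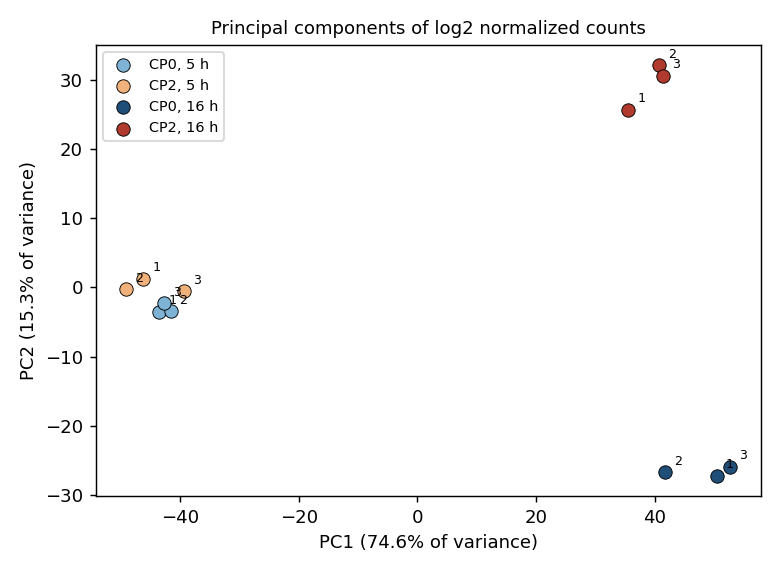
Principal components of log2(normalized count + 1) over 2693 genes; each point is 1 of the 12 libraries, coloured by group and marked with its replicate number. PC1 (74.6% of variance) separates the times, and PC2 (15.3%) separates CP2 from CP0 at 16 h.

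The first question was how transcript levels at 16 h differed between cultures with and without calcium palmitate. Of 2693 genes tested, 1664 (61.8%) changed, 844 upward and 820 downward. Among genes that met the rule for naming, the largest rises were in CG447_14180, from 2629 ± 2552 normalized counts in CP0 to 32886 ± 10827 in CP2 (SD, n = 3), and in its neighbour CG447_14185, from 739.4 ± 653.3 to 9979 ± 4613. Both belong to a run of 8 neighbouring genes that rose together with a median log2 change of 2.52. The largest falls were in CG447_06950, from 1191 ± 222.5 to 25.1 ± 17.36, and in CG447_06955, from 9351 ± 2051 to 189.5 ± 105.1. These lie in a run of 6 genes with a median log2 change of -5.22. The log2 change was 4.02 ± 0.49 (SE, adjusted p = 2.02e-05) for CG447_14180 and 3.97 ± 0.49 (adjusted p = 2.39e-05) for CG447_14185. It was -5.78 ± 0.47 (adjusted p = 9.48e-07) for CG447_06950 and -5.73 ± 0.30 (adjusted p = 3.74e-08) for CG447_06955. Single libraries moved 3 of these sizes by over 1.5 times with no call lost: without replicate 2 of CP0 at 16 h the log2 changes of CG447_14180 and CG447_14185 were 4.78 and 4.66, and without replicate 2 of CP2 at 16 h that of CG447_06950 was -5.12.

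At 5 h, CG447_06950 and CG447_06955 were low in both groups, at 7.466 and 68.25 normalized counts in CP0 and 8.934 and 69.45 in CP2. In CP0 they rose with time, by 7.13 and 7.06 on the log2 scale. In CP2 the log2 change of CG447_06955 was 1.31 (adjusted p = 0.00156). That of CG447_06950 was 1.12, a marginal call (adjusted p = 0.0462) that was lost in 11 of 12 fits with 1 library left out; without replicate 1 of CP2 at 16 h the change was 0.61 (adjusted p = 0.202) and without replicate 2 it was 1.79 (adjusted p = 0.00027). CG447_14180 was already abundant at 5 h, with 39078 ± 115.9 normalized counts in CP0 and 55384 ± 5366 in CP2. Between the times its log2 change was -4.33 in CP0 and -0.81 in CP2 (adjusted p = 0.149). Without replicate 2 of CP0 at 16 h it was -5.09 in CP0, and the change of -0.81 in CP2 was called (adjusted p = 0.00492).

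Many of the genes called at 16 h lay in runs of neighbouring genes. The longest run that fell held 31 genes, with a median log2 change of -1.84 and a range of -4.58 to -0.37. A run of 14 genes fell with a median of -2.04, from a median value of 15160 in CP0 to 4952 in CP2. The longest run that rose held 24 genes with a median of 1.49. These genes were abundant at 5 h, with a median value of 41100 in CP0, and stood at 4925 in CP0 and 12880 in CP2 at 16 h. A run of 22 genes rose with a median of 2.95, from a median value of 48.35 to 406.7, and a run of 16 genes rose with a median of 2.27. In all, 682 called genes (41%) lay in 88 runs of at least 5 genes, against at most 19 such runs in 1000 shuffled gene orders. Among neighbouring pairs in which both genes were called, 87.1% of 1161 pairs changed in the same direction, against at most 54.8% in the shuffles.

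Of the 1664 genes, 706 changed at least 2-fold, 418 upward and 288 downward, and the median size of the called changes was 0.88 on the log2 scale. In 1613 genes (59.9%) the groups did not overlap, against 10% by chance for 3 libraries against 3. The CP2 libraries at 16 h had fewer reads than the others, and 96.6% of the called genes remained called in the same direction with every library thinned to the smallest total, 12428812 reads.

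**Figure D2:**
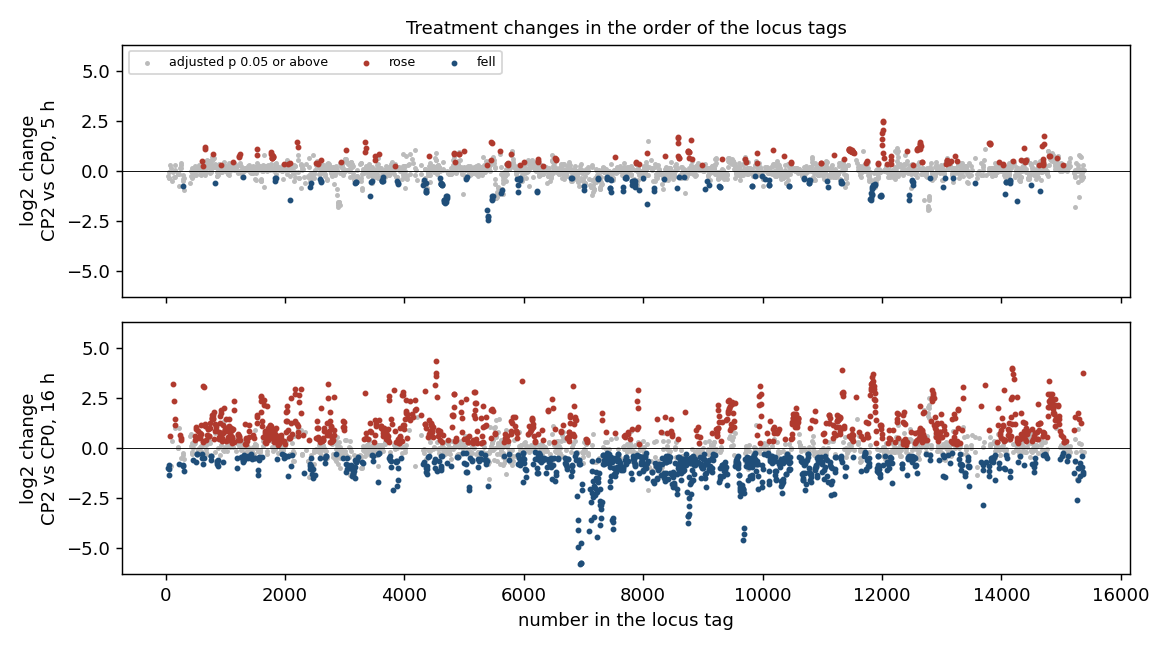
Log2 change of CP2 against CP0 at 5 h (top) and 16 h (bottom) for each of 2693 genes, ordered by the number in the locus tag; red points rose, blue points fell and grey points had an adjusted p of 0.05 or above. At 16 h 844 genes rose and 820 fell, many in runs of neighbouring tags, against 178 and 172 at 5 h.

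The same comparison at 5 h rests on libraries whose labels conflict, since those titled CP2 at 5 h also carry a field that states no calcium palmitate. Here 350 genes (13%) changed, 178 upward and 172 downward. The largest rises were in CG447_12015, from 1273 ± 74.47 normalized counts in CP0 to 7210 ± 1154 in CP2 (SD, n = 3), and its neighbour CG447_12010, from 908 ± 86.43 to 4983 ± 733.8. Their log2 changes were 2.49 ± 0.34 (SE, adjusted p = 0.000798) and 2.45 ± 0.34 (adjusted p = 0.000817), in a run of 8 genes with a median of 1.73. At 16 h the log2 differences of the same genes between CP2 and CP0 were -0.40 (adjusted p = 0.324) and -0.37 (adjusted p = 0.356), and without replicate 3 of CP0 at 16 h they were called, at -0.87 (adjusted p = 0.0067) and -0.85 (adjusted p = 0.00715). The largest falls were in CG447_05405, from 3949 ± 429.2 to 1164 ± 1038, and CG447_05400, from 15840 ± 1401 to 4863 ± 3876.

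The log2 changes of CG447_05405 and CG447_05400, in a run of 4 genes, were -2.46 ± 0.73 (SE, adjusted p = 0.0455) and -2.33 ± 0.67 (adjusted p = 0.0414), and these calls were marginal. Replicate 3 of CP2 at 5 h held 146.7 and 666.9 normalized counts of the pair, against 1124.8 and 5611.2 in replicate 1 and 2221.9 and 8310.3 in replicate 2. Without replicate 3 the log2 changes were -1.31 and -1.21, and both calls held (adjusted p = 0.0342 and 0.00214). Without replicate 2 they were -3.27 and -3.03 (adjusted p = 0.00804 and 0.00988). Both calls were lost with edgeR (adjusted p = 0.0909 and 0.0722), with DESeq2 (0.0722 and 0.0504) and with only the 5 h libraries in the fit (0.0709 and 0.0734). Over all alternatives the adjusted p ranged from 0.00804 to 0.127 and from 0.00214 to 0.115. At 16 h the log2 differences of the pair between CP2 and CP0 were -1.86 (adjusted p = 0.0418) and -0.58 (adjusted p = 0.464). With 1 library left out, the 16 h call of CG447_05405 was lost in 8 of 12 fits, and CG447_05400 was called in 1. With all libraries the interaction was called for neither, at 0.59 (adjusted p = 0.652) and 1.74 (adjusted p = 0.146).

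With 1 spread fitted to all groups, runs of at least 5 genes were fewer at 5 h than at 16 h, 12 against 88. The longest run that rose held 18 genes with a median log2 change of 1 and a range of 0.89 to 1.08, from a median value of 8303 in CP0 to 16520 in CP2. The longest run that fell held 12 genes with a median of -1.48 and a range of -1.61 to -1.25, from 6149 to 2117. In all, 97 called genes (27.7%) lay in these 12 runs, against at most 1 such run in the shuffles, and 95.7% of 184 neighbouring called pairs changed in the same direction. At least 2-fold changes were found in 93 genes, 46 upward and 47 downward. The groups did not overlap in 1346 genes (50%), against 10% by chance, most of them with no call.

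The main fit shares 1 spread between all groups. The median SD among replicates was 0.075 in CP0 and 0.115 in CP2 at 5 h, against 0.209 and 0.201 at 16 h. Counts at 5 h and 16 h are therefore not on an equal footing. The count at 5 h depended on the fit. With only the 5 h libraries it was 898, of which 346 were among the 350. It was 193 to 475 when 1 library was left out. It fell by over 1.5 times without any CP0 library at 5 h (209, 193 and 201 without replicates 1, 2 and 3) and without replicate 1 (219) or 3 (223) of CP2 at 5 h; with libraries scaled to equal totals the 178 genes that rose and 172 that fell became 121 and 176.

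**Figure D3:**
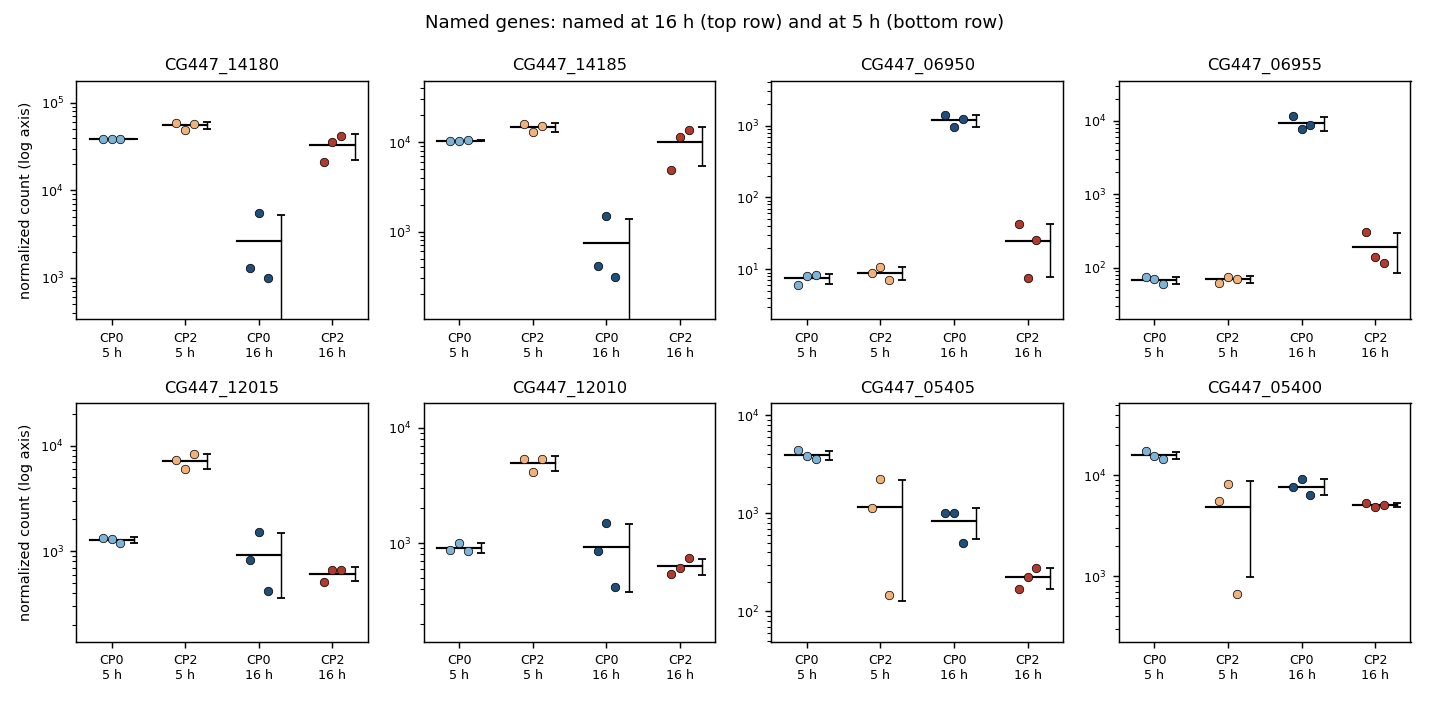
Normalized counts on log axes of the genes named at 16 h (top row) and at 5 h (bottom row) in the 4 groups; points are the 3 libraries of a group, horizontal lines their mean and vertical bars the SD, whose lower end runs off the axis where the SD is close to the mean. CG447_06950 and CG447_06955 were highest in CP0 at 16 h, with means of 1191 and 9351.

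Whether the treatment change differed between the times was tested by the interaction, in which the libraries labelled CP2 at 5 h take part. It was called for 1266 genes, 603 with a higher log2 change at 16 h than at 5 h and 663 with a lower one. The pair with the largest positive differences was CG447_11840, with a log2 difference of 4.48 ± 0.32 (SE, adjusted p = 1.48e-06), and CG447_11830, with 4.47 ± 0.28 (adjusted p = 4.97e-07). In CP2 relative to CP0, CG447_11840 fell by 1.23 on the log2 scale at 5 h and rose by 3.25 at 16 h, and CG447_11830 fell by 0.92 and rose by 3.56. The fall of CG447_11830 at 5 h was not called without replicate 3 of CP0 at 5 h (adjusted p = 0.0514). CG447_11840 stood at 21.87 ± 5.274 normalized counts in CP0 and 214.5 ± 23.87 in CP2 at 16 h (SD, n = 3). They belong to a run of 21 genes with a median log2 difference of 3.84. The largest negative differences were again in CG447_06950, with -6.01 ± 0.67 (adjusted p = 2.94e-05), and CG447_06955, with -5.75 ± 0.42 (adjusted p = 1.62e-06). Without replicate 2 of CP2 at 16 h the difference of CG447_06950 was -5.34.

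The treatment changes at 5 h and 16 h share no libraries, and across genes their correlation was weak (Pearson r = 0.13, Spearman rho = 0.21); genes are not independent replicates. Of the 233 genes called at both times, 159 (68.2%) changed in the same direction and 74 in opposite directions, and the interaction was called for all 74. Genes that rose at both times numbered 69, against 55.8 for independent lists, and genes that fell at both numbered 90, against 52.4. Of the 1664 genes called at 16 h, 1137 also had a called interaction.

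**Figure D4:**
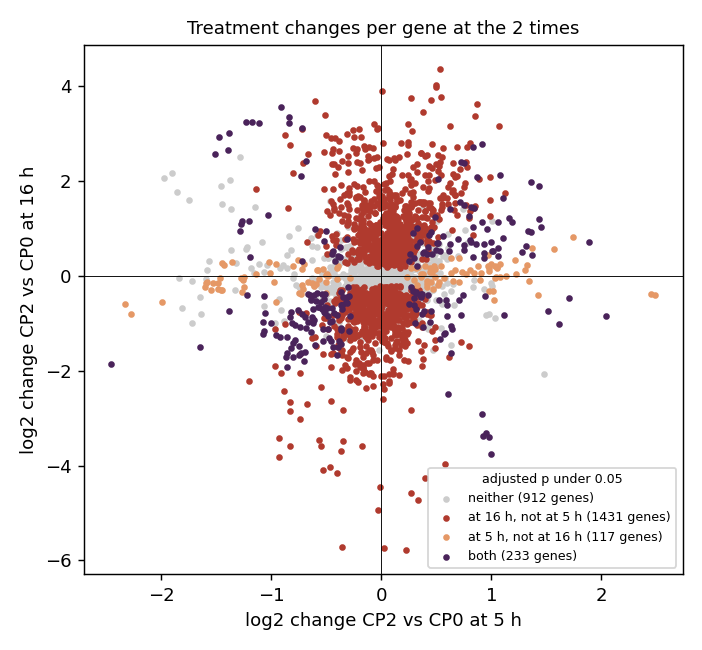
Log2 change of CP2 against CP0 at 5 h (x axis) and at 16 h (y axis) for 2693 genes, coloured by the time at which the gene was called. There were 1431 genes called at 16 h and not at 5 h, 117 at 5 h and not at 16 h, and 233 at both.

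Between 5 h and 16 h, most genes changed in cultures without calcium palmitate. In CP0, 1031 genes rose and 1020 fell, 76.2% of those tested. CG447_02210 rose from 200.2 ± 12.04 to 62358 ± 22930 normalized counts (SD, n = 3), and CG447_02205 from 210.6 ± 33.61 to 63801 ± 23953. Their log2 changes were 8.20 ± 0.28 (SE, adjusted p = 2.38e-10) and 8.16 ± 0.33 (adjusted p = 6.16e-10), in a run of 5 genes with a median of 7.25. CG447_12775 fell from 88301 ± 15678 to 279.3 ± 110.5 and CG447_12780 from 2214 ± 358.7 to 5.433 ± 3.651, the latter with 16 reads over the 3 libraries at 16 h. Their log2 changes were -8.38 ± 1.47 (adjusted p = 0.000213) and -8.59 ± 1.45 (adjusted p = 0.000154), and that of CG447_12780 was -7.39 with a pseudocount of 8. The spread behind these standard errors is shared by all groups, and replicate 3 of CP2 at 5 h held 720 normalized counts of CG447_12775, against 109326 and 139160 in replicates 1 and 2.

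The longest run that fell with time in CP0 held 33 genes with a median log2 change of -2.69. A run of 25 genes fell with a median of -6.62, from a median value of 511.1 to 7.034. In all, 1081 called genes (52.7%) lay in 131 runs of at least 5 genes, against at most 40 such runs in the shuffles. At least 2-fold rises numbered 617 and falls 637.

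In CP2, 1030 genes rose and 1037 fell between the libraries labelled 5 h and those at 16 h. CG447_02210 and CG447_02205 again rose most, to 132373 ± 34439 and 142729 ± 38660 normalized counts (SD, n = 3), with log2 changes of 8.14 ± 0.28 (SE, adjusted p = 3.27e-10) and 7.94 ± 0.33 (adjusted p = 1.07e-09). CG447_10285 fell from 49065 ± 3029 to 340.1 ± 4.157, a log2 change of -7.17 ± 0.22 (adjusted p = 1.36e-10). CG447_05800 fell from 465.4 ± 138.5 (adjusted p = 2.83e-07). With 2 reads in all at 16 h and 2 libraries at 0, the ratio of its levels was 404, with a 95% exact Poisson interval of 112 to 3330 that covers counting error only. The 33 genes that formed the longest falling run in CP0 also fell in CP2, with a median of -1.46. A run of 24 genes rose with a median of 1.40 and a run of 20 with a median of 2.25.

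Time changes in CP0 and CP2 share no libraries and were correlated across genes (Pearson r = 0.80, Spearman rho = 0.75). Of 1691 genes called in both, 1533 (90.7%) changed in the same direction, with 772 that rose in both against 394.3 for independent lists and 761 that fell in both against 392.8. A further 76 rose in CP0 and fell in CP2, and 82 did the opposite. Of the 637 genes that fell at least 2-fold in CP0, the interaction was called upward for 256 and downward for 41; their median log2 change was -2.02 in CP0 and -1.41 in CP2. Picked instead by CP2, the 607 genes that fell at least 2-fold there had the interaction called upward for 90 and downward for 198, with median log2 changes of -1.64 in CP2 and -1.60 in CP0. Of the 617 genes that rose at least 2-fold in CP0, it was called for 324, 26.5% of them upward, and of the 598 that rose at least 2-fold in CP2, for 330, 69.4% of them upward. The direction of these counts thus turned with the group by which the genes were picked.

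All time changes are relative to the median gene. With libraries scaled to equal totals, the median log2 change of all genes was -0.47 in CP0 and -0.41 in CP2, and the genes that rose and fell numbered 700 and 1353 in CP0 and 700 and 1306 in CP2.

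The treatment changes at 16 h and the time changes in CP0 both use the CP0 libraries at 16 h. Their correlation across genes was -0.40 and their covariance was -0.797. In simulations with no effect the covariance was -0.046, a difference of -0.751. The simulated correlation was -0.616. It comes from noise alone, without the variance of real changes, so it is not a level to set beside -0.40. Genes that rose with time in CP0 and were lower in CP2 at 16 h numbered 474, against 313.9 for independent lists, and genes that fell with time and were higher in CP2 numbered 454, against 319.7. The 3 control libraries cannot be split into 2 sets of at least 2, so part of these numbers may come from the shared controls. In the simulations that part of the covariance was small, -0.046 beside -0.797 in the data.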

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

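The tests of a straight time path at 16 h and all tests on replicate 3 of CP2 at 5 h, and the simulated sets without an interaction, were chosen after the results were seen, and the thinning of reads was added after the data were seen.

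The treatment change differed between 16 h and 5 h, by the interaction test in limma, for 1266 genes. Splits of the 12 libraries, 100 with the real one included, were drawn with time and treatment fitted beside each split. Of these, 1 gave as many calls, the smallest share that 100 draws can give, and the highest other gave 467. The real interaction stays in the spread of the other splits, so 467 is not a count with no interaction. In 100 simulated sets with the effects of time and treatment but no interaction, the highest count was 265. Among the 1266 were genes named for the treatment change at 16 h or at 5 h. Their differences in log2 change, 16 h minus 5 h, were 3.52 for CG447_14180, 3.48 for CG447_14185, -6.01 for CG447_06950, -5.75 for CG447_06955, -2.89 for CG447_12015 and -2.82 for CG447_12010. The larger positive differences of CG447_11840 and CG447_11830 are given above. Without replicate 2 of CP2 at 16 h the difference of CG447_06950 was -5.34, and without replicate 2 of CP0 at 16 h those of CG447_14180 and CG447_14185 were 4.28 and 4.16. All rest in part on the libraries labelled CP2 at 5 h, whose labels conflict. No formal outlier test was made in groups of 3 libraries.

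For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many calls. Every other split mixes the groups compared, which puts the real difference into the spread. The low counts of the other splits are therefore not a level for no effect. The real count was 1664 at 16 h, and the highest other split gave 3 (313 at an unadjusted p under 0.05). It was 350 at 5 h, against 0 (45 unadjusted), 2051 for time in CP0, against 0 (35), and 2067 for time in CP2, against 0 (136), all with limma.

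The breadth of the 16 h difference, 1664 genes, comes with CP2 libraries of 12428812 to 15261281 reads against 22527494 to 23866105 in CP0. With all libraries thinned to 12428812 reads, 96.6% of the called genes remained called in the same direction, which argues against the lower number of reads as the cause. Thinning cannot test any other difference between the libraries that came with the lower depth, since all 3 CP2 libraries at 16 h share it. If the CP2 cultures were only earlier on the course from 5 h to 16 h, treatment should oppose nearly all time changes in CP0. Of the genes called for both treatment and time in CP0, 70.3% moved in opposite directions. A delay along a straight path is thus not the whole difference. The shared CP0 libraries at 16 h push the changes apart by a covariance of -0.046, simulated with no effect, against -0.797 in the data. The share of 70.3% does not show that a delay is a part of the difference. A delay along a curved path, with genes that peak between the samplings, remains open. So does a response to calcium palmitate, which the design names and cannot separate from a change in growth, since growth was not analysed here.

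Replicate 3 of CP2 at 5 h held 72 genes more than 2-fold below the mean of replicates 1 and 2, 28 of them more than 8-fold below, and 16 genes more than 2-fold above. The low genes were clustered, 47 of the 72 in 9 runs of at least 3 genes. With time in CP0, 26 of the 28 also fell, and of the 72, 51 fell and 5 rose. Of all 2693 genes tested, 1020 fell with time in CP0. CG447_12775 was 171-fold lower, at 720 normalized counts. RNA of a 16 h culture, or a swapped 16 h library, could lower these genes but would raise those that climb with time, and 41 genes that rose at least 16-fold in CP0 had a median deviation of only 0.24 on the log2 scale (quartiles 0.05 and 0.45). A shift far along the whole course is also disfavoured. Of the 126 genes that fell at least 8-fold in CP0, 14.3% were over 2-fold lower. The median deviation of the 126 was -0.01 on the log2 scale (quartiles -0.23 and 0.14). A smaller shift, which lowers mainly the genes that fall early, could pass this 2-fold cut and remains open. A state of this culture that affects a limited set of gene runs stays open, and no biological explanation was tested.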

How the results depend on the processing

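Thinning was added after the data were seen; the other alternatives were planned. At 16 h the count of 1664 was 1667 with edgeR, 1697 with DESeq2, 1401 with only the libraries compared and 1632 thinned, and 706 with a 2-fold limit. At 5 h the 350 genes became 367 with edgeR, 498 with DESeq2, 340 thinned, 898 with only the 5 h libraries and 93 with a 2-fold limit. The range on leaving out 1 library was 193 to 475, with counts of 209, 193 and 201 without replicates 1, 2 and 3 of CP0 at 5 h and 219 and 223 without replicates 1 and 3 of CP2 at 5 h. The smaller fit drops the 16 h libraries, whose replicates are more spread, and 346 of the 350 genes were kept; the highest count, 475, came without replicate 1 of CP2 at 16 h. The cause of these differences was not tested. With a 2-fold limit the interaction went from 1266 to 630 genes, time in CP0 from 2051 to 1254 and time in CP2 from 2067 to 1205. Under the other alternatives run, the counts at 16 h, for the interaction and for time stayed within 1.5 times. The correlation of treatment changes at 5 h and 16 h, 0.13, was 0.159 with edgeR and with DESeq2 and 0.095 to 0.176 on leaving out 1 library; the cause was not tested. With a replicate block the counts were 1617, 300, 1197, 2034 and 2032 (16 h, 5 h, interaction, time in CP0, time in CP2). The replicate numbers do not pair the libraries: same-numbered deviations correlated at -0.19 to 0.1, and 1 of 12 libraries correlated best with its own number.

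In the comparisons that named them, of 216 values of the 16 named genes outside the left-out libraries, 6 lost the call and 0 reversed; of 240 with a library left out, 14 lost it and 0 reversed. All these losses were of CG447_05405 and CG447_05400 at 5 h. Both lost it without any CP0 library at 5 h (adjusted p 0.104 to 0.127), without replicate 1 of CP0 at 16 h (0.0615 and 0.0577) and without replicates 2 or 3 of CP2 at 16 h (0.0554 to 0.0626). CG447_05405 also lost it without replicate 1 of CP2 at 5 h (0.067) or replicate 2 of CP0 at 16 h (0.0503). The gene list tests and their alternatives were not run, as tags are not paired with names. Depth limits few named genes: CG447_05800 and CG447_12780 had 2 and 16 reads in their low groups.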

Other observations

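The fit of a wave along the tag order and its 3 tests were chosen after the plot of changes by tag number had been seen, and a first look at 4 of the 5 comparisons came before the tests were written down.

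The balance of genes that rose and fell in CP2 at 16 h varied along the tag numbering. With the numbering cut into 6 equal stretches, the median log2 change was 0.34, 0.08, -0.18, -0.50, -0.02 and 0.22 in order. The genes that rose numbered 194, 156, 97, 74, 158 and 165, and those that fell 68, 82, 173, 266, 154 and 77. At 5 h the medians were 0.11, 0.03, -0.02, -0.04, 0.00 and 0.08.

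A single cosine wave over the whole numbering had a height of 0.45 on the log2 scale at 16 h and took up 8.5% of the variance of the changes. In 2000 shuffles of blocks of 50 neighbouring genes the highest wave was 0.37 (permutation test of blocks, p = 0.0005, the smallest the shuffles can give; adjusted p over the 5 comparisons = 0.0012). Over block lengths of 25, 50, 100 and 200 genes, at most 0.05% of shuffles gave as large a wave, and with ranks in place of log2 changes at most 0.1% did, which argues against a chance order of gene runs and against a few strongly changed runs. The wave was 0.09 at 5 h (adjusted p = 0.0175), 0.38 for the interaction (0.0012), 0.33 for time in CP2 (0.0231) and 0.09 for time in CP0 (0.816). For time in CP2 it did not hold with ranks in 3 of the 4 block lengths, where 5.45% to 6.65% of shuffles were as large. In simulations over 2693 genes the fit called 6% of 50 sets without a wave and 100% of 50 sets with a height of 0.5. These sets used blocks of 50 genes only, and their changes were uncorrelated from 10 genes apart onward. At 16 h the correlation in the data was still 0.27 at 10 tags and 0.14 at 20, so the 6% may not carry over.

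If tag numbers start near the origin of replication and follow 1 circular chromosome, neither of which was checked here, a candidate explanation is gene copy number, which is higher near the origin in replicating cells. A simple version, in which CP0 cultures stopped replicating between 5 h and 16 h and CP2 cultures did not, requires the opposite wave in the time changes of CP0. The height there at the place of the 16 h peak was -0.06, with a shuffle SD of up to 0.15. This argues against an opposite wave as high as the 0.45 seen at 16 h. The cut set for the test was 50% of that height, and the spread is too wide to decide on a wave of that size. The same version requires no such wave in the time changes of CP2. The height in CP2 at that place was 0.31, with a shuffle SD of up to 0.13, which goes against it. That wave did not hold with ranks at most block lengths, so a version with a smaller opposite wave in CP0 stays undecided. Regulation of genes that happen to be grouped by position remains open as well.

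Correlations of log2 changes between genes fell with distance along the tags. At 16 h r was 0.68 for adjacent tags, 0.32 at 5 tags and 0.14 at 20, and at 5 h it was 0.68, 0.21 and 0.04. In none of the 5 comparisons were 186 genes called.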
